A study of Mus musculus with 14 samples.

How the data were processed

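RNA from 8 aortas with perivascular fat and from 6 preparations of CD115+ blood cells was amplified from 1 ng per sample with a whole-transcript kit and labelled with biotin, per the labels' protocols. Groups, genotypes and replicate numbers came from the sample titles and genotype labels. CD115+ ApoE-deficient replicates 3 and 4 were pools of littermates per the labels, and all other samples were single RNA preparations. The labels call the aorta samples separate samples, so the p-values measure the spread between mice as far as each sample is 1 mouse.

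The authors deposited 1 table of log values for 33793 probe sets on 14 arrays, which were read here as log2 values. The log base, the array normalization and the summarisation of probes are not given in the sources used here. For every one of the 33793 probe sets the median over the 8 aorta arrays and the median over the 6 CD115+ arrays was 0 within 1e-06, so the values had been centred per probe set and tissue before deposition. The scale within an array is therefore known only up to the log base, the direction is that of signal, and levels between genes and between tissues are lost. Only a coarse bound on level, described below, was inferred from the rounding of the values. Array medians were 0.0041, 0.0022, -0.0045 and 0.0002 in double-deficient aorta replicates 1 to 4, 0.0012, -0.0064, 0.0052 and -0.0024 in ApoE-deficient aorta, 0.0040, -0.0077 and -0.0042 in double-deficient CD115+ cells, and 0.0024, 0.0026 and 0.0015 in ApoE-deficient CD115+ cells. The SD over probe sets ran from 0.267 to 0.464 in aorta and from 0.134 to 0.249 in CD115+ arrays. No background signal or detection call was part of the values used, so a weakly expressed gene cannot be told from background.

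A platform annotation paired 23521 probe sets with 1 gene symbol and 1814 with several; 8458 had none listed. Probe sets with several symbols or none were left out. This gave 22180 genes, of which 1082 had more than 1 probe set, and 21994 were found in the GRCm38.p6 gene table, which was used only for names and for neighbours of Ltbr.

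The design fixed before the data were examined had a filter on mean level, the probe set of highest level per gene and a mean-variance trend in the empirical Bayes step. Centred values hold no level, so none of these could be used as meant. Instead every gene was kept, a gene was the mean of its probe sets, and the trend became an alternative. Genes were tested within each tissue with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. The difference between tissues was tested in 1 fit of the 4 group means. Gene lists (37, of 5 or more measured members, fixed before the data were examined: pathways, and markers of the cell types these samples could hold) were tested with camera at a preset correlation of 0.01, and again with camera at an estimated correlation, with fry, and with an exact two-sided permutation of the list mean over the splits of the samples. For the difference between tissues the genotype labels were permuted within each tissue, which supposes no genotype difference in either tissue. Fry tests whether a list moves, not whether it differs from other genes. Genes near Ltbr were compared with all others by Fisher's exact test, two-sided.

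The genes named were taken by a rule fixed before the data were examined. It names Ltbr, then in each tissue and direction the 12 genes of largest difference among those past the threshold whose groups do not overlap, filled to 12 by smallest p and then given as values, up to 4 members of smallest p per list, and up to 5 genes per sign of difference between tissues, filled to 3. Gene models without a proper name, microRNA and other small RNA genes, olfactory, vomeronasal and taste receptors and pseudogenes were excepted.

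The scripts were tested on simulated data with the spread of these arrays on the 22180 genes. For aorta 60.3% of genes changed by 1 on the log2 scale, 89.4% of those changed by 2 and 98.5% of those changed by 4 were recovered, with 14 unchanged genes called. For CD115+ cells the shares were 80.9%, 95.5% and 100%, with 10 unchanged genes called. In each tissue 68, 66 and 66 genes were changed by 1, 2 and 4. The adjusted threshold depends on how many genes change, so the shares hold for these numbers only. They do not show that such changes would be found where fewer genes change. A shifted list was called, and 0 of 20 unchanged lists, in both. Genes were drawn independently and lists at random in this simulation. Its list results therefore do not show how often lists of genes that move together are called wrongly.

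To find out which genes had a high signal, the rounding of the values was used. Values stored as 32-bit numbers have a step of 2 to the power -20 at levels from 8 to 16 and of 2 to the power -21 at levels from 4 to 8, and the difference of 2 such numbers keeps the step. A probe set with at least 5 usable arrays in a tissue, all on the coarser step, was taken to have a level of at least 8. A gene was taken as high if any of its probe sets was. This assumes that the levels were stored with that precision and centred once. It also assumes that the centre kept the step, although a median over 8 or 6 arrays is the mean of 2 middle values. Otherwise genes at a high level would be missed. Chance gives such a pattern for 2.41% (aorta) and 15.27% (CD115+) of the probe sets called high with all arrays usable. By this measure 14.9% of genes judged in aorta and 9.89% in CD115+ cells were high.

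Alternatives tried were quantile normalization within each tissue, centring each array on its median, the trend, robust eBayes, 1 fit of all 14 arrays, array weights, the replicate number as a block, weight 2 for pooled preparations, the brown adipocyte list mean as a covariate, an unadjusted p under 0.05 with at least a 1.5-fold difference, other windows and thresholds near Ltbr, and leaving out each replicate. The probe set of largest SD, a restriction to genes at the higher step, and the exact permutation of list means were chosen after seeing the data.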

Results

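Gene expression was measured on biotin-label arrays in 2 tissues of male mice that lacked either apolipoprotein E alone (ApoE-deficient) or both apolipoprotein E and the lymphotoxin beta receptor (double-deficient). Mice without ApoE build up cholesterol-rich remnant particles in plasma and develop atherosclerosis. The lymphotoxin beta receptor, encoded by Ltbr, is a receptor of the tumour necrosis factor family that stromal and myeloid cells use to receive signals from lymphocytes. All mice ate a high-fat, high-cholesterol diet for 4 weeks and were 12 weeks old. The aorta was taken with the fat around it, from 4 double-deficient mice and 4 ApoE-deficient littermates. Cells carrying CD115, the receptor for macrophage colony-stimulating factor that blood monocytes bear, were pulled from blood with magnetic beads, giving 3 double-deficient and 3 ApoE-deficient preparations. Of these, 2 ApoE-deficient preparations (replicates 3 and 4) were each a pool of animals. The labels do not say whether aorta and blood came from the same mice. Each value is a log2 signal relative to the median of its probe set over the arrays of its tissue, so levels cannot be compared between genes or tissues. The number of arrays limits the precision. Differences are double-deficient minus ApoE-deficient, on 22180 genes.

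The first comparison asked what the loss of the receptor changed in the aorta. Ltbr itself was 3.12-fold lower in the double-deficient aortas (log2 difference -1.64, SE 0.17). Its values averaged -0.97 ± 0.34 (SD, n = 4) in double-deficient and 0.68 ± 0.16 (SD, n = 4) in ApoE-deficient samples, and the groups did not overlap. The exact permutation test of this single gene gave the smallest two-sided p that 4 against 4 samples allow (0.02857). Its adjusted p over all genes in limma was 0.068. Where the 1 probe set of Ltbr lies relative to the deleted part of the gene is not in the labels, so the residual signal has no known meaning.

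**Figure D1:**
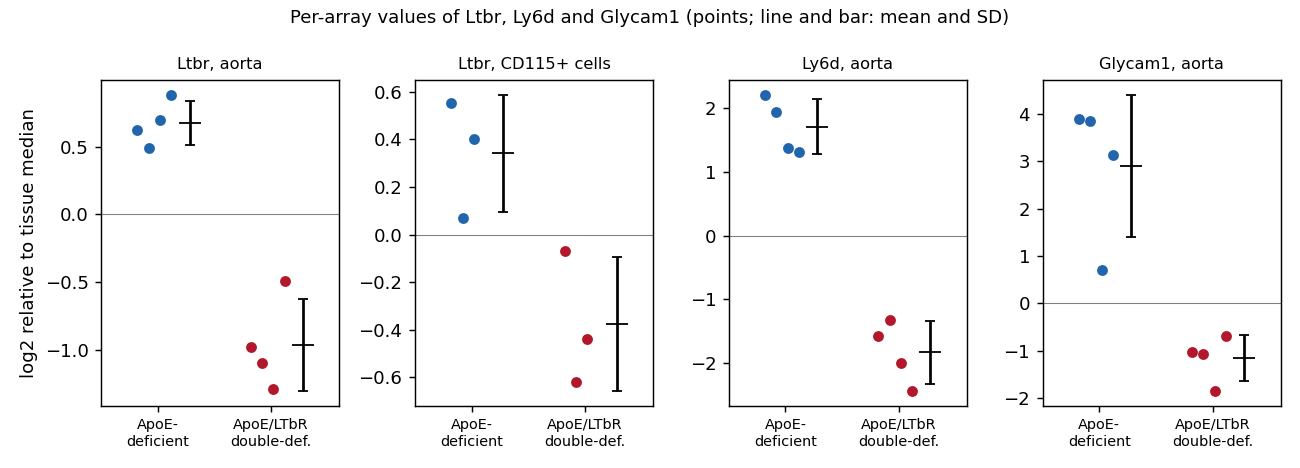
Values of Ltbr in aorta and CD115+ cells, and of Ly6d and Glycam1 in aorta, one point per array, on a log2 scale relative to the tissue median of each gene. The line and bar give the mean and SD of each group. In all 4 panels every double-deficient array lies below every ApoE-deficient array, with Glycam1 in ApoE-deficient replicate 3 at 0.70 against 3.13 to 3.90 in the other ApoE-deficient arrays.

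Genes of lymphocytes and of lymphoid tissue were lower in the double-deficient aortas. Ly6d, a surface protein of lymphoid cells, fell by 3.54 on the log2 scale (SE 0.29, adjusted p = 0.0495, limma) and was the 1 gene past the threshold over all genes, and 0 genes were higher. Its call was lost with robust eBayes, array weights and the probe set of largest SD, and in most fits without 1 array. Of the T cell list, 16 of 16 genes had a negative difference, with a mean of -1.22, and 13 fell with the adjustment made over the list alone. Cd4 and Cd8a, the co-receptors of helper and cytotoxic T cells, differed by -1.24 (SE 0.18) and -1.86 (SE 0.28). Cd3e, a chain of the T cell receptor complex, differed by -1.90 (SE 0.46) and Bcl11b, a transcription factor of the T lineage, by -0.73 (SE 0.14). The list was called by camera (adjusted p = 8.45e-17), but not with an estimated correlation between genes (adjusted p = 0.19 with an estimated correlation). Of the B cell list, 15 of 16 genes were negative (mean -1.56) and 12 fell adjusted over the list alone. Among them were Cd22 at -1.70 (SE 0.41), Cd79a at -2.21 (SE 0.58), a signalling chain of the B cell receptor, and the complement receptor Cr2 at -2.41 (SE 0.64). Its camera call (adjusted p = 5.35e-13) was also lost (adjusted p = 0.213 with an estimated correlation).

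Other lists of immune cells went the same way. Some lists share members, so they are not separate lines of evidence. Cr2 is in both the B cell and the lymphoid stroma list, and Themis and Cd8b1 are in both the T cell and the thymocyte list. The list of class II antigen presentation genes had 9 of 9 negative members (mean -1.21), of which 4 fell adjusted over the list alone. These included H2-DMb2 at -3.05 (SE 0.56) and H2-Oa at -2.33 (SE 0.61), both of which regulate peptide loading (adjusted p = 1.47e-08, adjusted p = 0.213 with an estimated correlation). The list of lymphoid stroma and high endothelial venules, the vessels through which lymphocytes enter lymph nodes, had a mean of -0.70 and 4 members that fell adjusted over the list alone. Glycam1, an adhesion ligand made by these venules, differed by -4.06 (SE 0.69), and Chst4, a sulphotransferase that modifies such ligands, by -0.83 (SE 0.23, list adjusted p = 9.98e-05, adjusted p = 0.227 with an estimated correlation). In the list of the lymphotoxin receptor pathway (mean -0.50, 14 of 16 negative), 5 fell adjusted over the list alone. They included Ltbr itself, its ligand gene Ltb at -2.66 (SE 0.67), made mainly by lymphocytes, and Tnfrsf13c, the B cell receptor for BAFF, at -1.15 (SE 0.33, list adjusted p = 2.41e-06, adjusted p = 0.213 with an estimated correlation). In the thymocyte list 4 of 8 fell adjusted over the list alone (mean -0.67). Among these were Dntt, the polymerase that adds bases to antigen receptor joints, at -1.72 (SE 0.42), and Themis at -1.06 (SE 0.27, list adjusted p = 0.000215, adjusted p = 0.213 with an estimated correlation).

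Natural killer, plasma cell and dendritic cell lists were called lower with fewer members past the threshold adjusted over the list alone. The natural killer list had 13 of 13 negative members (mean -0.61, 0 past the threshold adjusted over the list alone). Klrd1 stood at -1.89 (SE 0.53) and Nkg7 at -0.91 (SE 0.28, adjusted p = 1.32e-07, adjusted p = 0.213 with an estimated correlation). The plasma cell list (mean -0.57, 0 of 10 past the threshold adjusted over the list alone) held Mzb1, with means of -0.14 ± 0.15 in double-deficient and 1.86 ± 1.51 in ApoE-deficient samples (SD, n = 4 each), and Jchain, the joining chain of secreted antibodies, at -2.03 (SE 0.75, adjusted p = 0.00198, adjusted p = 0.441 with an estimated correlation). Without ApoE-deficient replicate 2 the plasma cell mean was -0.37. In the dendritic cell list (mean -0.40, adjusted p = 0.00302, adjusted p = 0.371 with an estimated correlation) Siglech, a marker of plasmacytoid dendritic cells, fell to a difference of -1.19 (SE 0.33) adjusted over the list alone. Batf3, a factor of conventional dendritic cells, rose by 0.66 (SE 0.18) with the same adjustment. The dendritic cell call was lost without ApoE-deficient replicate 1 (mean -0.27). Proliferation genes had 21 of 21 negative members (mean -0.47, 0 past the threshold adjusted over the list alone), with Birc5 at -0.89 (SE 0.28) and Rrm2 at -0.65 (SE 0.22, adjusted p = 2.97e-09, adjusted p = 0.213 with an estimated correlation). Of the ribosomal protein list 5 of 17 fell adjusted over the list alone, Rpl10a by 0.34 and Rplp0 by 0.59 (mean -0.22, adjusted p = 7.52e-09, adjusted p = 0.19 with an estimated correlation). Processed pseudogenes can share signal with these genes. The macrophage list did not differ beyond its spread (mean 0.11, adjusted p = 0.265), with Mrc1 at 0.33 (SE 0.15) and Gpnmb at 0.60 (SE 0.28), or 0.19 and 0.38 without double-deficient replicate 1. Its mean was -0.05 without that replicate, and it was called higher without double-deficient replicate 2 (0.22) and without ApoE-deficient replicate 1 (0.19).

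**Figure D2:**
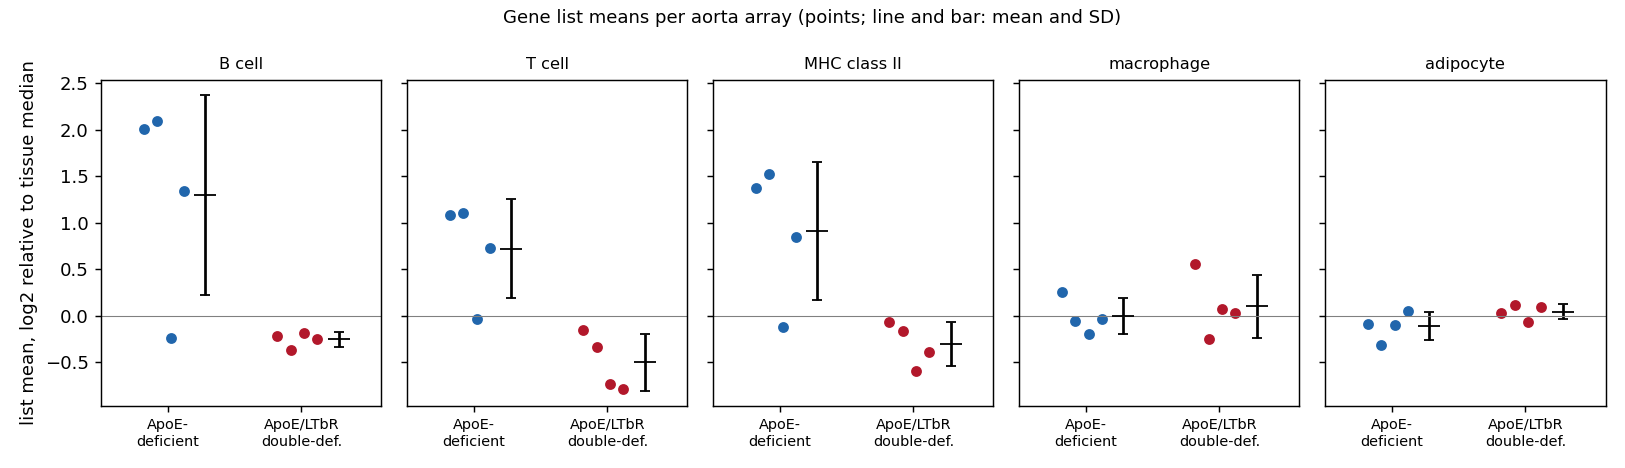
Means of 5 gene lists in each of the 8 aorta arrays, in log2 units relative to the tissue median of each gene. Points are arrays. The line and bar give the mean and SD of the group (n = 4). The B cell mean of ApoE-deficient replicate 3 (-0.24) lies among the double-deficient arrays (-0.37 to -0.19), whereas the other ApoE-deficient arrays lie between 1.34 and 2.09.

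The lymphocyte lists were not equally high in all ApoE-deficient aortas. The B cell mean was 1.34 to 2.09 in replicates 1, 2 and 4 and -0.24 in replicate 3, within the double-deficient range. The class II mean was 1.38, 1.52 and 0.85 against -0.12. The T cell mean was 1.08, 1.11 and 0.72 against -0.04 in that replicate, which still lay above the 4 double-deficient arrays (-0.15 to -0.79). Without ApoE-deficient replicate 3, 69 genes were lower and 5 higher. Leaving out each of the other arrays gave 0 to 2 lower. Of these 8 fits Ly6d passed in those without ApoE-deficient replicate 3 or without double-deficient replicate 4.

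Genes of the vessel wall and of fat were higher as lists, by small amounts. Smooth muscle genes had 13 of 15 positive members (mean 0.26, Actg2 0.53, SE 0.15, Mylk 0.31, SE 0.10, adjusted p = 9.98e-05, adjusted p = 0.371 with an estimated correlation). Endothelial genes had 16 of 17 (mean 0.18, Eng 0.39, SE 0.10, adjusted p = 0.00152, adjusted p = 0.19 with an estimated correlation). Matrix genes had 15 of 16 (mean 0.26, Col5a2 0.60, SE 0.17, Timp1 1.39, SE 0.47, adjusted p = 0.0017, adjusted p = 0.443 with an estimated correlation). Adipocyte genes had 10 of 13 (mean 0.15, the lipases Lipe 0.23, SE 0.07, and Lpl 0.28, SE 0.09, adjusted p = 0.00123, adjusted p = 0.336 with an estimated correlation). For fatty acid synthesis genes it was 15 of 15 (mean 0.45, Fasn 0.36, SE 0.20, Acaca 0.53, SE 0.28, adjusted p = 8.64e-05, adjusted p = 0.45 with an estimated correlation). In each of these 5 lists 0 genes passed the threshold adjusted over the list alone. Single arrays carried much of them: the smooth muscle mean was 0.16 without double-deficient replicate 2, and the adipocyte and fatty acid synthesis means were 0.09 and 0.28 without ApoE-deficient replicate 2. The matrix mean was 0.14 without double-deficient replicate 1, where its call was lost. Without ApoE-deficient replicate 1 Fasn was at 0.24 and Acaca at 0.34. Sterol-sensing LXR target genes (mean 0.18, Apoc1 0.50, SE 0.19, adjusted p = 0.00924, adjusted p = 0.213 with an estimated correlation), fatty acid oxidation (mean 0.17, adjusted p = 0.019, adjusted p = 0.497 with an estimated correlation) and nerve genes (mean 0.34, adjusted p = 0.00912, adjusted p = 0.443 with an estimated correlation) were also called higher. Among the last, Prph, an intermediate filament of peripheral neurons, rose by 0.75 (SE 0.19) adjusted over the list alone. Skeletal muscle genes were called lower (mean -1.09, Mylpf -1.96, SE 1.07, Mybpc2 -1.17, SE 0.47, adjusted p = 4.86e-05, adjusted p = 0.45 with an estimated correlation). Their means ran from -1.24 to 1.80 among ApoE-deficient arrays and from -1.03 to 1.17 among double-deficient arrays, so that the groups overlapped. The lists of immediate early genes (mean -0.21, adjusted p = 0.45 with an estimated correlation), chemokines and their receptors (mean -0.21, Ccl12 -0.93, SE 0.21, adjusted p = 0.45 with an estimated correlation) and interferon response (mean -0.19, adjusted p = 0.45 with an estimated correlation) were called lower by camera at adjusted p of 0.00742, 0.0244 and 0.0265. Calls were lost without double-deficient replicate 2 for the nerve (mean 0.20), fatty acid oxidation (0.14), interferon (-0.10), chemokine (-0.12) and immediate early (-0.13) lists, and without ApoE-deficient replicate 3 for LXR targets (0.15). Other arrays also ended calls when left out: ApoE-deficient replicate 1 for fatty acid oxidation (0.13), interferon (-0.07) and chemokines (-0.13), ApoE-deficient replicate 2 for fatty acid oxidation (0.13) and chemokines (-0.15), ApoE-deficient replicate 4 for immediate early genes (-0.08), and double-deficient replicate 4 for fatty acid oxidation (0.09) and chemokines (-0.14). Without double-deficient replicate 1 the chemokine and immediate early means were -0.37 and -0.38, and without ApoE-deficient replicate 3 the chemokine mean was -0.33. The skeletal muscle mean was -1.72 without ApoE-deficient replicate 1 and -0.71 without ApoE-deficient replicate 3.

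Beyond the lists, the genes with the smallest p in each direction were given as values, since none but Ly6d passed. Lgals4, an intestinal-type galectin, differed by 1.17 (SE 0.11, adjusted p = 0.0541), Bmpr2, a receptor of bone morphogenetic proteins, by 0.71 (SE 0.07, adjusted p = 0.068) and Nbea by 0.69 (SE 0.07, adjusted p = 0.068). The adhesion gene Cdh19 differed by 1.15, Cda by 0.85, Pcsk6 by 0.72, and Arhgef12, Dlg1, Ankrd46, Jade1, Zfhx4 and Oplah by 0.55 to 0.62. On the other side stood Terc, the RNA template of telomerase, at -1.83, Trp53inp1 at -1.23, the histone gene H2ac15 at -1.18, Rassf2 at -0.66, Ccnd1 at -0.45, and the ribosomal Rps26 and Rps13 at -0.46 and -0.33. H2ac15 belongs to a family of near-identical copies and its signal is uncertain. Treml4, a receptor of Ly6C-low monocytes, fell by 0.65 (SE 0.13) adjusted over its list alone.

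At an unadjusted p under 0.05, 1713 genes differed in aorta (867 higher, 846 lower), against 1109 given by chance. Of them 121 were at least 1.5-fold higher and 327 at least 1.5-fold lower. The groups did not overlap for 4.3% of genes, where chance gives 2.86%. Of 37 lists 23 were called by camera, 8 higher and 15 lower, 0 of them with an estimated correlation. Directional fry called 1 and fry's test for change in either direction 7, and the exact permutation of list means reached its smallest p for 4 (T cell, thymocyte, ribosomal protein and LXR target lists, 0.02857, adjusted p = 0.244 over the 37 lists). The other lists, not called, had means of 0.08 (oxidative phosphorylation), -0.10 (canonical NF-kB), -0.11 (neutrophil), 0.18 (cholesterol synthesis), 0.12 (brown adipocyte), -0.18 (Ly6C-low monocyte), -0.14 (leukocyte adhesion), 0.09 (circadian clock), -0.13 (platelet), -0.16 (mesothelial), 0.26 (cardiac muscle), 0.18 (erythroid) and -0.07 (Ly6C-high monocyte, whose median was 0.12). Of the 14 lists not called in aorta, 13 moved by over 1.5 times when 1 array was left out. Cholesterol synthesis and oxidative phosphorylation, for example, were at 0.03 and 0.03 without ApoE-deficient replicate 1, brown adipocyte and NF-kB at 0.03 and -0.02 without double-deficient replicate 4, erythroid at 0.04 without double-deficient replicate 1 and platelet at -0.03 without double-deficient replicate 3. Some of these lists grew and were called without another array. Cholesterol synthesis was at 0.34 without ApoE-deficient replicate 4 and oxidative phosphorylation at 0.15 without ApoE-deficient replicate 3. NF-kB was at -0.22 without double-deficient replicate 1 and brown adipocyte at 0.18 without double-deficient replicate 3.

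The second comparison asked the same of the CD115+ blood cells. In these cells the clearest list was that of interferon response genes. They were lower in the double-deficient preparations, with 16 of 16 negative members and a mean of -0.44. Of these 5 fell adjusted over the list alone: the antiviral Oas2 (-1.09, SE 0.27) and Bst2 (-0.49, SE 0.14), Usp18, which removes the ubiquitin-like ISG15 (-0.56, SE 0.07), Rtp4 (-0.95, SE 0.22) and the chemokine gene Cxcl10 (-0.48, SE 0.14). The list means were -0.48, -0.16 and -0.21 in double-deficient and 0.16, 0.11 and 0.18 in ApoE-deficient preparations (camera adjusted p = 6.86e-11, adjusted p = 0.351 with an estimated correlation). Among the genes of smallest p outside the list, Oas1g, of a family with similar copies, stood at -1.67 (SE 0.17) and Ifi205 at -1.67 (SE 0.25), both interferon-inducible. Genes of Ly6C-high monocytes, the inflammatory blood subset, had 14 of 14 negative members (mean -0.53), with Ly6c2 at -1.30 (SE 0.51), Chil3 at -1.27 (SE 0.44), Vcan at -0.89 (SE 0.35) and F13a1 at -0.44 (SE 0.18, adjusted p = 2.18e-05, adjusted p = 0.582 with an estimated correlation). Of them 0 passed adjusted over the list alone. Double-deficient replicate 1 carried much of this, since the list means were -0.82, -0.15 and -0.0033 in double-deficient and 0.30, -0.04 and 0.35 in ApoE-deficient preparations. Without that replicate the list mean was -0.28, and the differences of Ly6c2, Chil3 and F13a1 were -0.70, -0.83 and -0.28. Vcan was at -0.49 without ApoE-deficient replicate 4. Macrophage genes were lower too (15 of 18 negative, mean -0.21, the Fc receptor gene Fcgr1 -1.07, SE 0.32, the scavenger receptor gene Msr1 -0.45, SE 0.13, adjusted p = 0.00596, adjusted p = 0.582 with an estimated correlation), a call lost without double-deficient replicate 2 (mean -0.14). Of the macrophage genes 0 passed adjusted over the list alone.

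**Figure D3:**
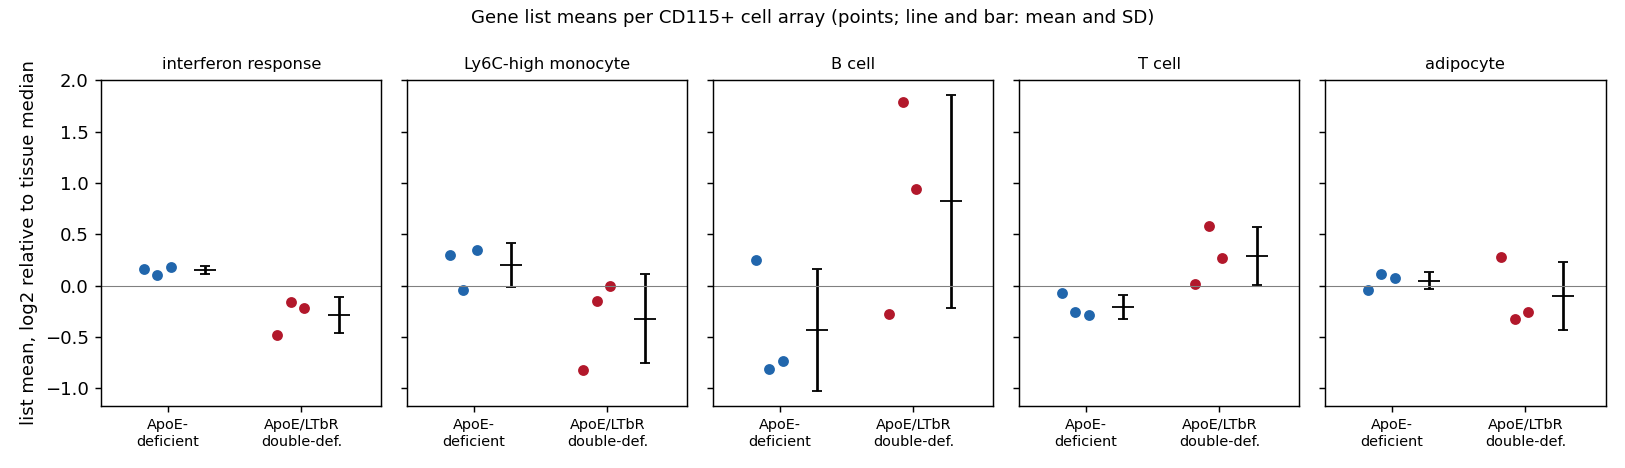
Means of 5 gene lists in each of the 6 arrays of CD115+ cells, in log2 units relative to the tissue median of each gene. Points are arrays. The line and bar give the mean and SD of the group (n = 3). Interferon means run from -0.48 to -0.16 in double-deficient and from 0.11 to 0.18 in ApoE-deficient arrays. The B cell mean of double-deficient replicate 1 (-0.27) lies far below those of replicates 2 and 3 (1.79 and 0.95).

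Lymphocyte genes were higher in these double-deficient preparations. The B cell list had 16 of 16 positive members (mean 1.25), with Blk at 1.44 (SE 0.46) and Bank1 at 1.92 (SE 0.78, adjusted p = 6.86e-11, adjusted p = 0.632 with an estimated correlation). The T cell list had 16 of 16 (mean 0.49, Lat 0.65, SE 0.22, Cd3g 0.82, SE 0.30, adjusted p = 8.81e-09, adjusted p = 0.471 with an estimated correlation). The class II list had 9 of 9 (mean 0.74, H2-Ab1 0.38, SE 0.14, H2-DMb2 1.41, SE 0.58, adjusted p = 1.31e-05, adjusted p = 0.744 with an estimated correlation). None of these genes passed a threshold adjusted over its list alone. The B cell mean was -0.27, 1.79 and 0.95 in the double-deficient and 0.25, -0.81 and -0.73 in the ApoE-deficient preparations, and the class II mean -0.24, 1.27 and 0.68 against 0.14, -0.35 and -0.29, so that both overlapped between the groups. Without double-deficient replicate 2 these differences were 0.77 and 0.38, with H2-DMb2 at 0.94 and Cd3g at 0.54, and without double-deficient replicate 1 the class II difference was 1.14. The T cell means did not overlap (0.02, 0.58 and 0.27 against -0.07, -0.26 and -0.28), which gives the smallest exact permutation p for 3 against 3, 0.1. The 2 pooled preparations, both ApoE-deficient, had the lowest means of all 6 in each of the 3 lists, so that pooling cannot be separated from this difference. Immediate early genes (mean 0.24, Egr1 0.51, SE 0.20, adjusted p = 0.002, adjusted p = 0.84 with an estimated correlation) and canonical NF-kB genes (mean 0.29, adjusted p = 0.0232, adjusted p = 0.582 with an estimated correlation) were called higher. Lists of matrix genes (mean -0.17, Col3a1 -0.31, SE 0.21), fatty acid oxidation (mean -0.13), fatty acid synthesis (mean -0.17), oxidative phosphorylation (mean -0.09), cholesterol synthesis (mean -0.12) and adipocytes (mean -0.15, Plin1 -0.25, SE 0.21, Retn -0.23, SE 0.15) were called lower at adjusted p from 0.00362 to 0.045, each at an adjusted p = 0.84 with an estimated correlation. These 8 calls were each lost without double-deficient replicate 2, without double-deficient replicate 3 and without ApoE-deficient replicate 3. Without double-deficient replicates 1, 2 and 3 and ApoE-deficient replicate 3 in turn, the means were 0.43, 0.16, 0.13 and 0.17 (immediate early), 0.46, 0.18, 0.25 and 0.28 (NF-kB), -0.27, -0.15, -0.10 and -0.14 (matrix), -0.24, -0.06, -0.09 and -0.10 (fatty acid oxidation), and -0.33, -0.07, -0.11 and -0.13 (fatty acid synthesis). They were -0.17, -0.04, -0.05 and -0.07 for oxidative phosphorylation, -0.21, -0.08, -0.06 and -0.09 for cholesterol synthesis, and -0.34, -0.03, -0.07 and -0.11 for adipocyte genes. These last 3 calls were also lost without ApoE-deficient replicate 4 (-0.07, -0.12 and -0.13). Member genes moved too. Without double-deficient replicates 1 and 2 Plin1 was at -0.48 and -0.13 and Retn at -0.41 and -0.13. Without double-deficient replicate 3 Plin1 was at -0.14. Without double-deficient replicates 1 and 3 Col3a1 was at -0.52 and -0.15, and without ApoE-deficient replicate 3 Egr1 was at 0.31. Double-deficient replicate 1 stood opposite to replicates 2 and 3 in the adipocyte mean (0.28 against -0.32 and -0.25).

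Ltbr was 1.64-fold lower in double-deficient CD115+ cells (log2 difference -0.72, SE 0.18, adjusted p = 0.976, limma). The groups did not overlap (-0.38 ± 0.28 against 0.34 ± 0.25, SD, n = 3 each), which gives the smallest exact permutation p that 3 against 3 samples allow, 0.1. Counts of genes past the threshold were 0 higher and 0 lower in limma, with a smallest adjusted p of 0.833, and 974 genes had an unadjusted p under 0.05 against 1109 given by chance. Of these, 54 were at least 1.5-fold higher and 18 at least 1.5-fold lower. Groups did not overlap for 9.16% of genes, where chance gives 10%. By smallest p, the higher genes were Wdr43 (0.33), Gstp2 (0.45, it has a near-identical copy), Aebp2 (0.37), Prickle3 (0.47), Ccndbp1 (0.33), the adenosine deaminase gene Ada (0.31), Ndc80 (0.32), Aff3 (1.40), Mtf2 (0.24), Mbtps2 (0.41), Taf1a (0.37) and Usp53 (0.42). The lower ones, besides Oas1g, Ifi205 and Usp18, were Mrps10 (-0.40), Tor3a (-0.41), Zfp933 (-0.49), the lactate receptor gene Hcar1 (-0.43), Yipf6 (-0.39), Emc8 (-0.31), Znfx1 (-0.29), Pigu (-0.38) and Arhgap42 (-0.57), all as log2 differences that did not pass.

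Of the 37 lists 14 were called in CD115+ cells, 5 higher and 9 lower, 0 with an estimated correlation and 0 by directional fry. With 3 against 3 samples the exact permutation of a list mean cannot go under 0.1. Fry's test for change in either direction called 1, the interferon list (adjusted p = 0.0146). Without double-deficient replicate 1 camera called 24 lists. Without double-deficient replicate 2 or without ApoE-deficient replicate 3 the count was 6, and without double-deficient replicate 3 it was 9. Lists that were not called had means of -0.13 (Schwann cell and neuron), 0.12 (thymocyte), -0.07 (mesothelial), -0.13 (smooth muscle, Tagln -0.30, SE 0.18), -0.10 (brown adipocyte), 0.06 (ribosomal protein), 0.12 (natural killer), -0.09 (endothelial), 0.07 (erythroid), 0.07 (leukocyte adhesion), 0.19 (neutrophil), 0.16 (dendritic cell), 0.10 (platelet), 0.11 (lymphotoxin receptor pathway), -0.03 (LXR target), -0.04 (skeletal muscle) and 0.12 (chemokine). Another 6 lay within 0.04 of 0, namely the proliferation, plasma cell, circadian clock, cardiac muscle, lymphoid stroma and Ly6C-low monocyte lists, whose mean, median and test did not all have one sign. Of these 23 lists, 22 moved by over 1.5 times when 1 array was left out, and Tagln was at -0.48 and -0.18 without double-deficient replicates 1 and 2.

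Genotype differences were then compared between the tissues. The T cell list moved apart: it was lower in double-deficient aorta (mean -1.22) and higher in double-deficient CD115+ cells (mean 0.49), a difference of -1.71 that gave the smallest p of the exact permutation within tissues (0.001429, adjusted p = 0.0264 over 37 lists). By camera it was not called with an estimated correlation (adjusted p = 0.0997 with an estimated correlation). The permutation supposes no genotype difference in either tissue, so a difference in aorta alone can give a small p. It does not show that the list rose in CD115+ cells, where the difference cannot be separated from pooling. The thymocyte list, which shares Themis and Cd8b1 with the T cell list, differed by -0.78 with the same permutation p (adjusted p = 0.172 with an estimated correlation). The B cell list differed by -2.81 (exact permutation p = 0.01143, adjusted p = 0.0846) and the class II list by -1.95 (exact permutation p = 0.01, adjusted p = 0.0846), neither past the threshold. No single gene passed in limma (0 in either direction, smallest adjusted p 0.219, 1530 at an unadjusted p under 0.05 against 1109 given by chance). The genes of smallest p were Nbea (0.76, SE 0.11), Zfhx4 (0.92, SE 0.14) and Lgals4 (1.06, SE 0.17) with a positive and Ly6d (-5.05, SE 0.82), Trp53inp1 (-1.95, SE 0.33) and Cd8a (-2.27, SE 0.39) with a negative difference of aorta minus CD115+ cells. Without aorta ApoE-deficient replicate 3 there were 30 such genes, without CD115+ double-deficient replicate 1 there were 58, and without aorta double-deficient replicate 2 there was 1. Across the 22180 genes, which are not independent replicates, the genotype differences of the tissues correlated at r = -0.265 (Spearman's rho -0.161). Of them 99 had an unadjusted p under 0.05 in both tissues, against 75.2 given by chance, and 27 of the 99 had one sign.

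The last comparison looked at the chromosomal neighbours of Ltbr, which in a backcrossed knockout can come from the donor strain. Distances were taken between gene midpoints in the GRCm38.p6 annotation. Among the 296 tested genes within 10 Mb of Ltbr, 9.46% had an unadjusted p under 0.05 in aorta, against 7.70% of the other genes (odds ratio 1.25, Fisher's exact p = 0.272). Within 5 Mb it was 22 of 180 (odds ratio 1.67, Fisher's exact p = 0.0338), and at an unadjusted p under 0.01 it was 9 of 180 (odds ratio 2.58, Fisher's exact p = 0.0113). The wider windows did not pass: the odds ratio was 1.53 within 10 Mb at an unadjusted p under 0.01 (Fisher's exact p = 0.208), and within 20 Mb it was 1.06 at 0.05 (Fisher's exact p = 0.712) and 1.44 at 0.01 (Fisher's exact p = 0.216). The genes within 5 Mb included lymphocyte genes such as Cd4 and Klrd1, which were lower. Pex5 and Cecr2, named after their values were seen, also lie there and were higher in aorta (0.57 and 0.52). In CD115+ cells Pex5 was at -0.06 and Cecr2 at 0.55. Fisher's test takes genes as independent, which lymphocyte genes that moved together are not. Its p-values were not adjusted over the windows, thresholds and tissues tried, so an excess within 5 Mb is not established. The source of such an excess was not tested. In CD115+ cells 3.38% of the genes within 10 Mb passed, against 4.40% of the others (odds ratio 0.759, Fisher's exact p = 0.475), and the other windows and thresholds gave Fisher's exact p of 0.38 or more.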

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

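The tests of macrophage genes, of array scaling and of thymocyte genes were chosen after their results were seen. The Glycam1 test and the counts over other splits of the samples were not.

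The T cell list (difference of aorta minus CD115+ cells -1.71, exact permutation p = 0.001429) and the thymocyte list (-0.781, the same p) were picked out by their permutation p for the difference between the tissues. These lists share Themis and Cd8b1. That permutation supposes no genotype difference in either tissue. In aorta the lymphocyte genes were lower in double-deficient samples by -1.22 (SE 0.31) for the T cell list and by -1.56 (SE 0.54) for the B cell list (8 arrays). A loss of leukocytes of every kind to the same extent is argued against, since the macrophage list moved by 0.11 (SE 0.19), 1.33 above the T cell list (SE 0.27). This rests on the macrophage list, whose mean was -0.05 without double-deficient replicate 1. The natural killer (mean -0.61), plasma cell (-0.57) and dendritic cell (-0.40) lists were lower too. Scaling of the arrays as the whole cause is argued against too, since the T cell difference was -1.12 (SE 0.27) after quantile normalization, a change of 0.10 (SE 0.12).

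A discrete lymphoid structure, such as a lymph node in the fat, that was dissected with some ApoE-deficient aortas only may account for the B cell part of the pattern: Glycam1, a gene of lymph node venules, was 3.83 to 4.59 above the highest double-deficient array in ApoE-deficient replicates 1, 2 and 4 but 1.40 above it in replicate 3. The bounds were written before the values of Glycam1 per array were seen, but after the B cell means had singled out replicate 3: up to 1 for such a structure and over 2 against it, with the value between them. A first version, also from before these values were seen, had the bound against it at 1, and under that version the value would count against such a structure. With the outcome resting on that choice, this and an effect of the receptor on lymphoid tissue cannot be told apart here. They are also not exclusive, since a structure missing from double-deficient aortas could itself be an effect of the receptor. For the thymocyte list such a structure stays open: replicate 3 had the highest mean of all 8 aortas (0.25, or 0.103 above the mean of the other ApoE-deficient arrays). This goes against a structure missing from replicate 3 as the source of the thymocyte genes. How far it bears on a lymph node cannot be told from the list mean. The list mixes genes of developing T cells with Themis and Cd8b1, which are also in the T cell list. The value is also from 1 array and lies within 2 SD of the double-deficient mean (-0.50, SD 0.40). The genotype itself stays open as an explanation.

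Dixon's test within the groups of 4 aortas picked out 8 of 200 groups, where chance gives about 10, so these flags are no more than chance gives. In ApoE-deficient replicate 3 the lymphoid stroma list mean was -0.133 against 0.63 to 0.76 in the other 3, and Klrd1 was -0.101 against 1.95 to 2.37. In double-deficient replicate 4 the skeletal muscle list mean was 1.17 against -1.03 to -0.91, Mylpf was 1.76 against -2.23 to -1.55, and Batf3 was 0.800 against 0.094 to 0.139. In double-deficient replicate 3 the mesothelial list mean was 0.793 against -0.20 to -0.15, in double-deficient replicate 1 the immediate early list mean was 0.422 against -0.31 to -0.21, and in ApoE-deficient replicate 4 Mylk was -0.0028 against -0.13 to -0.11.

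Over the 35 splits of the 8 aortas into 4 and 4, 2 gave as many genes past the threshold as the real one (1 gene; highest other 8), so chance is not excluded for this count. The split with 8 genes set double-deficient replicates 1 to 3 and ApoE-deficient replicate 1 against the rest. These 4 arrays also had the lowest skeletal muscle means (-1.24 to -0.91, against 0.58 to 1.80 in the others). As many lists as the 23 called were found in 5 of the 35 splits (highest other 27), so chance is not excluded for that count either. The 10 splits of the 6 CD115+ arrays are too few for a share under 0.05: 10 gave as many genes as the real 0 (highest other 0), and 4 gave as many lists as the real 14 (highest other 24). For genes whose difference differs between tissues the real count was 0, which any split reaches (100 of 100 drawn ones, highest other 9), so this count and the 10 of 10 above say nothing about chance.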

How the results depend on the processing

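The probe set of largest SD, the restriction to genes at the higher step and the exact permutation of list means were chosen after seeing the data; the planned filter on mean level, and the correlation over genes past it in both tissues, were not run because centred values hold no level, and the planned fits without filter, without trend and with the mean of all probe sets are the reported ones. Over all alternatives, the named genes kept their direction in every one. Of these results 1692 stayed on their side of the threshold, 28 moved past it and 9 lost it, all 9 of them Ly6d. No named gene but Ly6d passed in the reported analysis, so most of the 1692 are genes that stayed short of the threshold. These results are therefore no measure of stability. Apart from Ltbr, the genes were also named by their p-values in these same data. The trend, robust eBayes and the fit of all arrays together use the same differences, so direction could not turn there. Gene lists kept side and direction in 1054, moved past the threshold in 56, lost it in 100 and turned in 47. The cause was not tested unless stated.

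Counts in aorta (0 higher, 1 lower) became 0 lower with robust eBayes, the probe set of largest SD, array weights and only genes at the higher step, 11 higher and 8 lower in 1 fit of all 14 arrays, 1 higher and 2 lower with the brown adipocyte covariate, and 121 higher and 327 lower at an unadjusted p under 0.05 with 1.5-fold, a looser threshold. Leaving out single arrays gave 0 to 5 higher and 0 to 69 lower, both highest without ApoE-deficient replicate 3. Ltbr in aorta passed in the fit of 14 arrays (-1.64), with the covariate (-1.77), with the unadjusted threshold (-1.64), and without ApoE-deficient replicate 3 or double-deficient replicate 4 (range over single arrays left out -1.80 to -1.53), and its adjusted p was highest without ApoE-deficient replicate 4 (0.289). In CD115+ cells it passed at the unadjusted threshold (-0.72; range over arrays left out -0.87 to -0.59). The 23 lists called in aorta became 0 with an estimated correlation, 1 with fry and 4 with the exact permutation at an unadjusted p under 0.05 (0 of them adjusted), and 19 to 27 over arrays left out. In CD115+ cells 14 lists became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation, where 3 against 3 cannot pass, 22 with array weights, and 6 to 24 over arrays left out; its gene counts became 54 higher and 18 lower at the unadjusted threshold with 1.5-fold and were 0 otherwise. Genes whose difference differs between tissues (0) became 736 at that threshold and 0 to 58 over arrays left out. The correlation between tissues (-0.265) was -0.348 with array weights, -0.336 over genes at the higher step in both tissues and -0.363 to -0.118 over arrays left out. Near Ltbr in aorta the odds ratio became 1.67 in the 5 Mb window; in CD115+ cells it turned from 0.759 to 1.01 there.

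Replicate numbers are shared between groups, but deviations from the group means gave no clear sign of a pairing by number. Those of same-numbered aortas correlated at 0.166, -0.146, -0.140 and 0.064, and those of CD115+ preparations 1 and 3 at -0.469 and -0.292. Not every aorta correlated best with its own number. With so few pairs, a pairing cannot be excluded. With the replicate block aorta gave 0 genes higher, 1 lower and 25 lists, and Ltbr an adjusted p of 0.279; CD115+ cells gave 0 genes, 6 lists and -0.56 for Ltbr; 0 genes differed between tissues and the correlation was -0.265. List means that turned under the block in CD115+ cells were lymphoid stroma -0.021, plasma cell -0.063, natural killer -0.11, neutrophil -0.50, platelet -0.61, skeletal muscle 0.015, cardiac muscle 0.0077, chemokine -0.098, proliferation -0.052 and ribosomal protein -0.012.

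None of the lists that turned was called in the reported analysis, but 4 of the turned results were called the other way: the neutrophil and platelet lists under the block, the platelet list without double-deficient replicate 2 and the Ly6C-low monocyte list without double-deficient replicate 3. In aorta the brown adipocyte covariate gave Ly6C-high monocyte 0.017 and canonical NF-kB 0.0034. In CD115+ cells quantile normalization gave lymphoid stroma -0.0085, Ly6C-low monocyte -0.022, neutrophil -0.0021, platelet -0.086 and cardiac muscle 0.023, and array weights gave lymphoid stroma -0.011 and erythroid -0.0033. Over arrays left out, ranges that crossed 0 in aorta were macrophage -0.046 to 0.22, Ly6C-high monocyte -0.18 to 0.038, cardiac muscle -0.038 to 0.61, neutrophil -0.19 to 0.027 and mesothelial -0.40 to 0.10. In CD115+ cells they were lymphoid stroma -0.032 to 0.043, erythroid -0.086 to 0.19, plasma cell -0.029 to 0.088, natural killer -0.055 to 0.25, neutrophil -0.23 to 0.51, platelet -0.48 to 0.41, skeletal muscle -0.11 to 0.0021, cardiac muscle -0.10 to 0.065, chemokine -0.041 to 0.25, LXR target -0.062 to 0.0029, proliferation -0.040 to 0.034, ribosomal protein -0.0099 to 0.19, Ly6C-low monocyte -0.29 to 0.23 and leukocyte adhesion -0.048 to 0.22. No signal over background was part of the values, so what it limits could not be measured.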

Other observations

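All tests in this part were chosen after the data were seen.

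Genes of fat, smooth muscle and matrix lay on the coarser step in the CD115+ blood cell arrays more often than other genes. Of the adipocyte list, 10 of the 11 genes that could be judged lay on the coarser step that marks a level of at least 8 (Fisher's exact adjusted p = 1.3e-08 against all genes, of which 9.89% did), Adipoq, Fabp4, Plin1 and Retn among them. The same held for 6 of 12 smooth muscle genes, Acta2 and Myh11 included (adjusted p = 0.00208), 7 of 15 matrix genes (adjusted p = 0.00133) and 5 of 12 brown adipocyte genes, Ucp1 included (adjusted p = 0.0138). It held for 0 of 15 endothelial genes, the other list of the vessel wall, for 0 of 16 B cell, 0 of 14 T cell, 0 of 16 skeletal muscle and 0 of 11 cardiac muscle genes, and for 7 of 14 Ly6C-high and 9 of 13 Ly6C-low monocyte genes. The genes in this paragraph were chosen after their values were seen. A step unrelated to the expression level is argued against, since genes abundant in every cell lay on it far more often than all genes: 12 of 16 ribosomal protein genes (75%, adjusted p = 1.3e-08) and 14 of 17 oxidative phosphorylation genes (adjusted p = 1.54e-10). RNA of vessel or fat in these preparations is a candidate explanation that stays open. The means of the adipocyte, smooth muscle and matrix lists moved together, the lowest of the 3 correlations being 0.885 (exact permutation p = 0.025, adjusted p = 0.025, Spearman's rho 0.771 with exact permutation p = 0.103, and r = 0.999 without the 2 arrays farthest from the median; the other r were 0.981 and 0.921, exact permutation p = 0.00417 and 0.0111, adjusted p = 0.0125 and 0.0167). This was not particular to lists with genes on that step. Of the 11 lists with none, 6 correlated positively with the adipocyte mean (skeletal muscle r = 0.965, endothelial 0.909, cardiac muscle 0.843, mesothelial 0.789, erythroid 0.625, lymphoid stroma 0.594) and 5 negatively (lymphotoxin receptor pathway r = -0.936, B cell -0.874, plasma cell -0.817, T cell -0.767, thymocyte -0.649). The adipocyte mean followed the first principal component of the 6 arrays, with 52.0% of the variance (absolute r 0.992). Bead selection for CD115 would remove such cells, and no level of these genes in other blood cells was measured, so no biological explanation was tested. Some of these genes, such as Lpl, Fabp4 and Pparg, can also be expressed by monocytes and macrophages.

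The lower interferon genes of double-deficient CD115+ cells were looked at with that in mind. Dilution by fat or vessel RNA as the whole cause is argued against, since it would lower genes of every blood cell, while the T cell list moved 0.928 (SE 0.11) above the interferon list. Such a dilution would also raise the adipocyte, smooth muscle and matrix lists, whose means were lower (-0.15, -0.13 and -0.17). The contrast says nothing on dilution by lymphocyte RNA, which was not tested. The T cell and B cell means were higher in double-deficient preparations (0.49 and 1.25). A lower share of Ly6C-high monocytes stays open: with the Ly6C-high list mean as a covariate the difference went from -0.436 (SE 0.10) to -0.261 (SE 0.061), within 1 SE of -0.218, the bound written for this test. With 3 against 3 preparations chance stays open as well, and the genotype is one of the explanations left.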
